A study of Mus musculus with 10 samples.

How the data were processed

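Ventricle RNA from WT and Trbp-cKO mouse hearts was sequenced as mRNA (4 libraries, 2 weeks of age) and as small RNA (6 libraries, postnatal day 2.5). Per the labels' protocols, tissue was frozen, RNA was extracted with Trizol, and libraries were made with Illumina TruSeq RNA and TruSeq Small RNA kits. The submitters' processing notes name CASAVA 1.8.2, cutadapt 0.9.5, Bowtie 0.12.9, SAMtools 0.1.16, edgeR and the mouse build mm10, with no role for each. The counting step, its treatment of reads with several matches, its use of strand and the annotation release are not given in the sources used here. Group and replicate number came from the sample titles. The header of the authors' list of differential transcripts names day 16 where the labels say 2 weeks, and the labels were followed.

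The authors deposited raw counts per RefSeq transcript for the mRNA libraries and raw counts per hairpin and arm for the small RNA libraries, as the whole numbers and unequal column totals of the tables show. The deposited mRNA tables also hold a ratio of Trbp-cKO over WT and a p-value and q-value per transcript, per the file headers, and the deposited miRNA tables a log2 fold change with p-values and q-values per arm, per the file headers. These comparison values entered no test. They are set beside the counts of changed genes and arms in the last paragraph of the results, and the q-values also pick the transcripts whose replicate spread is given among the other observations. The authors' mean and scaled columns were not used.

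The mRNA table had 30635 transcript rows. Accessions of 30020 rows matched the RefSeq gene table of assembly GRCm38.p6, which shares its coordinates with mm10 and gave the gene positions. It named 3793 of the 3903 rows with a blank symbol and all 39 rows whose symbol had been turned into a date. The 110 rows left without a name were kept out of library sizes and tests, and held 0.117% to 0.140% of a library's counts. Isoforms of a gene carry nearly the same reads, so that the transcript with the highest total count was kept for each gene, which left 23360 genes (4274 had more than 1 row) and 10151184 to 13540495 counts per library. Genes that overlap others, or that share reads with near-identical copies such as the globins and Hspa8, are uncertain, because how such reads were counted is not known. The small RNA table had 849 hairpins and 1698 arms, of which 927 had a count in any library, and libraries held 2201143 to 3885375 counts. miR-143-3p alone held 16.1% to 21.2% of a library's counts.

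Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes or arms were filtered with filterByExpr, library sizes were scaled by TMM, and genotype was tested with the quasi-likelihood F-test (glmQLFit with robust dispersion, glmQLFTest) at a Benjamini-Hochberg adjusted p of 0.05. Each assay was fitted alone, since the assays differ in age. Arm shares were tested as the interaction of arm and genotype over hairpins with both arms expressed, with each library as a block. CPM values use the TMM-scaled library sizes, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.103 for mRNA and 0.158 for miRNA arms.

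Before the data were examined, 22 mRNA and 9 miRNA lists, the tests of the results, most alternatives and the rule for named genes were fixed. Lists with at least 3 tested members (21 and 8) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The estimated form also takes its degrees of freedom from the few libraries, so a call lost there need not be due to correlation. In fry, which tests whether a list moves one way without comparing it with other genes, the slow-twitch (adjusted p = 1.23e-04), cell-cycle (0.0414) and endothelial (0.0414) lists passed among the mRNA lists. Among the miRNA lists fry passed the myomiR (adjusted p = 0.00222), let-7 (0.0114), miR-17-92 (0.0209) and smooth muscle (0.0209) lists. Named mRNAs are Tarbp2 and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap of the genotypes, leaving out predicted gene names. Named as well are, per list, up to 4 passing members with the smallest p, or 2 where none passed, and all tested miR-208 and miR-499 targets. An item that this rule names is not reported here. Named miRNAs are the 8 largest rises and 8 largest falls with a mean of at least 10 CPM, all tested myomiRs, members of the other lists by the same rule, and the 6 hairpins with the smallest p in the arm test. Outside this rule, and after their values were seen, Myl2, Atp2a2, Myh7, Myom1, Actn2, Hbb-b2, Postn, Kcne1, the cell-cycle genes that did not pass, Tnni2, Nppa, Cacna1h, Acta1, Chrm2, Fgf13, miR-490-3p, the level of miR-361-5p and the arm share of miR-145a were chosen. The counts of miR-1a-2-5p and the level of miR-133a-1-5p were added in the same way.

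Alternatives were DESeq2 size factors in edgeR, total count scaling, DESeq2 1.42.0, no filter, a mean of at least 5 CPM, the replicate number as a block, leaving out each library, an adjusted p of 0.01, leaving miR-143-3p out of library sizes, and at least 10 counts in each arm. All transcripts instead of 1 per gene, separate library sizes for the arms, and leaving out erythroid genes were added after seeing the data. Without 1 mRNA library, 1 genotype is left with a lone library. The spread then comes from the other genotype alone, so calls gained or lost there are weak evidence. A planned test of seed sites in 3' untranslated regions was not run. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 5.80 to 201, so that none was treated as a duplicate.

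The steps were tested on simulated counts drawn from the real means, library sizes and common dispersion, in 20 draws for each part. Changed genes and arms were picked among those with a mean of at least 20 counts. Differences in spread from gene to gene were not simulated, so recovery and false calls hold for that simpler setting. The number of draws was raised from 1 after a first single draw of the arm test gave a larger share of false calls than the threshold allows. For mRNA, with 200 changed genes, 44.7% of the genes changed 1.5-fold, 90.0% of those changed 2-fold and 99.5% of those changed 4-fold were recovered, and 4.18% of the calls were false. For miRNA arms, with 60 changed, recovery was 48.2%, 91.2% and 100%, with 3.91% false calls. For arm shares, with 30 changed hairpins, 63.3% of 2-fold and 98.0% of 4-fold changes were recovered, with 3.59% false calls. With no change simulated, the mean number of calls per draw was 0.05 for mRNA, 0.1 for miRNA arms and 0 for arm shares. Lowering the cell-cycle list 2-fold gave its call in 20 of 20 draws, and 0.05 other lists per draw. Figures were drawn with matplotlib.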

Results

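RNA was sequenced from the heart ventricles of C57BL/6 mice that were wild type (WT) or carried a conditional knockout of Trbp (Trbp-cKO). Trbp, whose mouse gene symbol is Tarbp2, is a double-stranded RNA-binding partner of Dicer, the enzyme that cuts miRNA precursors. Messenger RNA was profiled at the age of 2 weeks in 2 WT and 2 Trbp-cKO libraries, and small RNA at postnatal day 2.5 in 3 WT and 3 Trbp-cKO libraries. The mRNA libraries held 10151184 to 13540495 counts over genes, with 1 transcript kept per gene, and the small RNA libraries held 2201143 to 3885375 counts over miRNA arms. Labels do not say whether replicates are separate animals, so each p-value measures only the spread between these libraries. Levels are given as counts scaled to library size (CPM), as mean ± SD over the libraries of a genotype, and log2 fold changes, Trbp-cKO over WT, with their standard error (SE).

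The first comparison asked how mRNA levels differed between Trbp-cKO and WT ventricles at 2 weeks. The targeted transcript, Tarbp2 (NM_009319, chromosome 15, 102516077 to 102523676 in GRCm38), fell 3.12-fold. It went from 12.1 ± 0.802 CPM in WT to 3.88 ± 0.0102 CPM in Trbp-cKO (n = 2 each), with both Trbp-cKO libraries below both WT libraries. Its log2 fold change was -1.64 ± 0.17 (edgeR quasi-likelihood test, adjusted p = 0.000653). The annotated span of Tarbp2 overlaps that of Map3k12, so that reads of the pair cannot be told apart where they overlap. Of the other 13 tested members of the list of miRNA-processing and effector genes, which includes Dicer1, Drosha and the Argonaute genes, 1 rose. That gene was Tnrc6c, at a log2 fold change of 0.25 ± 0.07 (edgeR adjusted p = 0.0485). Adjusted over the list alone, 2 members rose and 2 fell, and 1 of the 2 that fell was Tarbp2 itself. The Tnrc6c call was lost with DESeq2 size factors (edgeR adjusted p = 0.0517), with total count scaling (0.0913), at a mean of at least 5 CPM (0.0621), in DESeq2 (adjusted p = 0.236), without WT replicate 1 or 2 (edgeR adjusted p = 0.231 and 0.312) and without Trbp-cKO replicate 2 (0.141).

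Of the 10 largest falls, those of Myh7b, Hopx and Tnnc1 were the deepest. Myh7b (NM_001085378, chromosome 2, 155611243 to 155634307), a myosin heavy chain gene that carries miR-499 and overlaps Trpc4ap, fell 119-fold, from 191 ± 6.69 to 1.59 ± 0.283 CPM (edgeR adjusted p = 1.30e-09). Hopx (chromosome 5, 77086986 to 77115123), a homeodomain cofactor of heart development, fell 45.6-fold from 480 ± 2.98 to 10.5 ± 1.02 CPM. Tnnc1 (chromosome 14, 31208312 to 31211729), the troponin C of cardiac and slow skeletal muscle, fell from 1917 ± 75.8 to 147 ± 10.5 CPM (log2 fold change -3.70 ± 0.08). Tecrl, a reductase-family gene expressed in heart, fell 4.61-fold, and Hcn4, the main channel of the sinoatrial pacemaker current, fell 4.55-fold. The remaining 5 of the 10 largest falls were Iqgap3 (6.31-fold), Eprn (5.76-fold), Sh2d4a (4.94-fold), Cenpf (4.88-fold) and Ckap2l (4.69-fold). Cenpf encodes a kinetochore protein and Ckap2l a mitotic spindle protein. Over these 10 genes the edgeR adjusted p was at most 0.0122, the value for Sh2d4a.

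Among the rises, the transcript of Oprd1 (chromosome 4, 132110188 to 132144486), the delta opioid receptor, was 15.4-fold higher, at 0.985 ± 0.114 CPM in WT and 15.2 ± 0.371 CPM in Trbp-cKO (edgeR adjusted p = 1.02e-05). Ces1d (chromosome 8, 93166072 to 93197804), a carboxylesterase, rose 14.1-fold from 11.3 ± 0.345 to 160 ± 0.404 CPM. Shisa3 rose 7.73-fold, Pfkfb1, a glycolysis regulator whose span overlaps Apex2, 4.75-fold, and Ankrd63 4.02-fold. Phactr1, a phosphatase and actin regulator, rose 3.82-fold from 11.7 ± 0.513 to 44.8 ± 2.64 CPM. Scgb1c1 rose 3.54-fold, Asb4 3.12-fold and Thsd4 3.09-fold. Hspa8, the constitutive heat shock cognate chaperone, was 4.74-fold higher, but its count is uncertain because the gene has many near-identical processed copies that can share its reads. Over these 10 genes the edgeR adjusted p was at most 0.00246, the value for Pfkfb1.

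**Figure D1:**
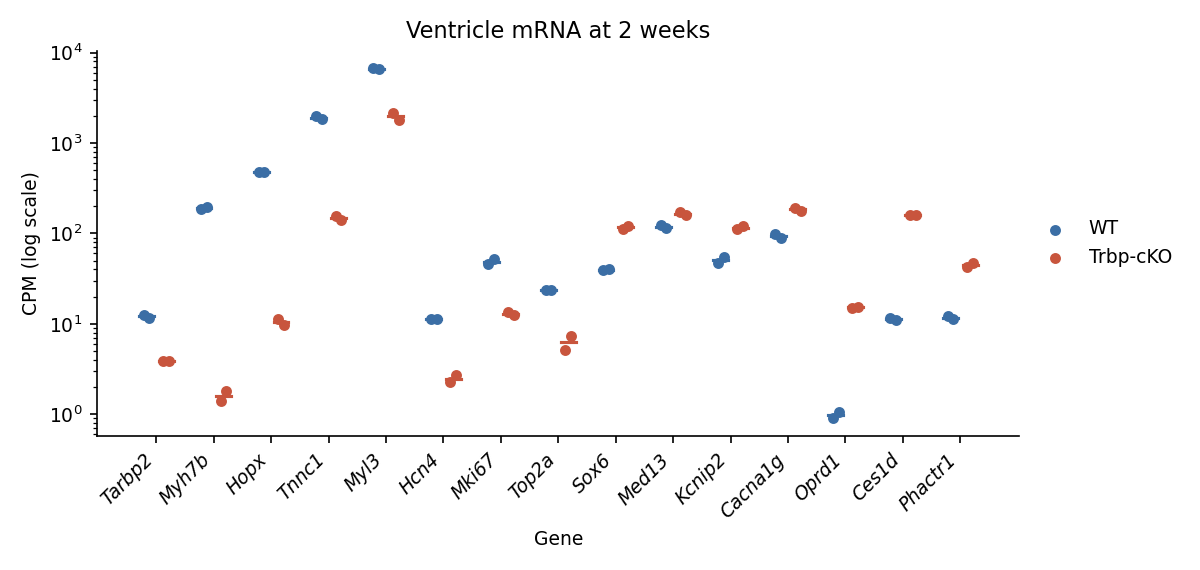
CPM on a log axis of 15 genes in each mRNA library at 2 weeks, with points for libraries (n = 2 per genotype) and short bars for the genotype means. Myh7b went from 191 to 1.59 CPM and Oprd1 from 0.985 to 15.2 CPM, with no overlap of the genotypes at any of the plotted genes.

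Genes of the slow-twitch fibre list changed in both directions. Of 11 tested, 4 fell, 2 rose and 5 did not pass (4 rose and 5 fell adjusted over the list alone). Beside Myh7b and Tnnc1, the ventricular and slow essential light chain gene Myl3 fell 3.35-fold from 6637 ± 126 to 1983 ± 231 CPM (edgeR adjusted p = 1.02e-05), and Myl2 fell by 0.31 on the log2 scale. The calcium pump gene Atp2a2 (log2 fold change 0.30 ± 0.05) and Tpm3 (0.60 ± 0.10) rose. Without WT replicate 1 or 2 the calls of Tpm3 (edgeR adjusted p = 0.109 and 0.0540), Myl2 (0.212 and 0.156) and Atp2a2 (0.204 and 0.211) were lost. Myh7, the slow myosin gene, was at 0.28 ± 0.09 and did not pass (edgeR adjusted p = 0.107), but passed with no filter (0.0491) and without Trbp-cKO replicate 1 (0.00297), and was at 0.14 without Trbp-cKO replicate 2. The list's median log2 fold change was -0.12 and its mean -1.06. Camera with a preset correlation put the list lower than other genes (adjusted p = 8.79e-06), and the adjusted p was 0.372 with an estimated correlation.

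Only 5 of the 15 genes of the fast-twitch fibre list were expressed highly enough to test, and 1 of them, Mybpc2, fell, at a log2 fold change of -0.46 ± 0.11 (edgeR adjusted p = 0.0313). That call was lost with DESeq2 (adjusted p = 0.208), without WT replicate 1 or 2 (edgeR adjusted p = 0.217 and 0.176) and without Trbp-cKO replicate 1 (0.126). Of the 5 genes 4 had a positive log2 fold change, and DESeq2 called 2. Tnni2, the fast skeletal troponin I gene, was at 4.13 ± 0.58 and did not pass in edgeR (adjusted p = 0.0809), but passed in DESeq2 (adjusted p = 4.38e-09). It was at 3.70 without Trbp-cKO replicate 1 and at 4.47 without Trbp-cKO replicate 2. Adjusted over the list alone, 2 rose and 1 fell. The median of the list was 0.63, and camera did not place it apart from other genes (adjusted p = 0.127), though it did without WT replicate 1 (camera adjusted p = 0.0233) and without Trbp-cKO replicate 1 (camera adjusted p = 1.21e-04).

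The cardiac sarcomere list moved in both directions, with 6 of 15 genes risen and 4 fallen (the same counts adjusted over the list alone). Tcap, the titin cap gene, rose from 708 ± 12.6 to 1249 ± 65.2 CPM (log2 fold change 0.82 ± 0.07, edgeR adjusted p = 2.02e-04). Myh6, the main adult myosin heavy chain gene of the mouse heart, rose from 33109 ± 102 to 43400 ± 1216 CPM (0.39 ± 0.05). Csrp3, the muscle LIM protein gene, fell by 0.52 and Mybpc3, the cardiac myosin-binding protein C gene, by 0.47 on the log2 scale. The other 2 that fell were Myom1 (-0.27 ± 0.07) and Actn2 (-0.25 ± 0.07). Myh6, Csrp3, Mybpc3, Myom1 and Actn2 lost their calls without WT replicate 1 and without WT replicate 2, with edgeR adjusted p between 0.0553 and 0.383. Camera gave the list an adjusted p of 0.619.

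In the list of stress-induced and fetal cardiac genes, 1 of 14 rose and 2 fell (the same adjusted over the list alone), and the list was not set apart by camera (adjusted p = 0.862). Without Trbp-cKO replicate 1 camera placed it higher (adjusted p = 3.85e-04). Ccn2, a matrix-associated growth factor gene, rose from 115 ± 9.79 to 170 ± 16.5 CPM. Fhl1, a LIM-domain gene, fell from 178 ± 0.324 to 131 ± 3.17 CPM, and the stress cytokine gene Gdf15 fell from 2.53 ± 0.694 to 0.838 ± 0.129 CPM. Ccn2 lost its call without WT replicate 1 (edgeR adjusted p = 0.0993), Fhl1 without either WT library (0.0674 and 0.0648), and Gdf15 with DESeq2 (adjusted p = 0.223) and without any 1 of the 4 libraries (edgeR adjusted p from 0.0569 to 0.259).

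Most cell-cycle genes fell. Of 23 tested, 19 fell and none rose (21 fell adjusted over the list alone), all 23 had a negative log2 fold change, and the median was -1.57. The proliferation marker Mki67 fell 3.75-fold from 48.8 ± 4.30 CPM in WT (edgeR adjusted p = 1.03e-05), and Top2a, the topoisomerase of dividing cells, fell 3.84-fold from 23.9 ± 0.0258 to 6.22 ± 1.46 CPM. The replication helicase genes Mcm2 and Mcm5 fell 3.06-fold and 3.25-fold. Members that did not pass were Ccne1, Ccne2, Mcm7 and Pcna, with log2 fold changes of -1.80, -0.60, -0.39 and -0.18. Ccne1 was at -3.20 and passed without Trbp-cKO replicate 1 (edgeR adjusted p = 0.0171), was at -1.08 without Trbp-cKO replicate 2, and passed with no filter (0.0349). Without WT replicate 1 or 2 Mcm7 was at -0.64 or -0.11, and without Trbp-cKO replicate 1 Pcna was at -0.11. Camera put the list lower than other genes (adjusted p = 3.36e-32), and the adjusted p was 0.372 with an estimated correlation (0.198) and few degrees of freedom.

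Markers of blood were lower in the same libraries. Erythroid genes had a median log2 fold change of -0.47, the value of the alpha globin copies, and 5 of 7 fell (5 adjusted over the list alone). Alas2, the heme synthesis enzyme of red cell precursors, fell from 47.7 ± 1.10 to 34.1 ± 4.58 CPM. The alpha globin genes Hba-a1 and Hba-a2 held identical counts in every library, so that the copies cannot be told apart, and each fell from 218 ± 31.2 to 158 ± 1.32 CPM. The beta globin genes Hbb-bt and Hbb-b2, which are near-identical, each fell by 0.25 on the log2 scale. Each call was lost without WT replicate 2 and without Trbp-cKO replicate 1. The globin calls were also lost without Trbp-cKO replicate 2, and those of Alas2, Hbb-bt and Hbb-b2 without WT replicate 1 (edgeR adjusted p over these fits from 0.0688 to 0.261). In DESeq2, Alas2 (adjusted p = 0.0529), Hbb-bt (0.236) and Hbb-b2 (0.240) did not pass. Camera put the list lower (adjusted p = 4.87e-04, and adjusted p = 0.698 with an estimated correlation). The median, the counts and camera take globin copies as separate genes, so that they rest on fewer measurements than 7.

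Of 23 extracellular matrix genes tested, 5 fell, none rose and 18 did not pass (8 fell adjusted over the list alone). The median log2 fold change was -0.16, and 6 of the 23 had a positive log2 fold change. The fibrillar collagen genes Col1a1 (366 ± 36.4 to 236 ± 33.3 CPM), Col1a2 (460 ± 49.6 to 314 ± 27.6 CPM), Col3a1 (1454 ± 141 to 1099 ± 118 CPM) and Col5a2 (132 ± 1.14 to 107 ± 8.02 CPM) were among the 5, with Postn (-0.56 ± 0.12 on the log2 scale), which encodes a matrix protein of fibroblasts. Camera gave an adjusted p of 0.00889, which became an adjusted p of 0.897 with an estimated correlation. The list's call also ended without WT replicate 1 (camera adjusted p = 0.549) or without Trbp-cKO replicate 1 (0.131), and none of the 5 genes passed without WT replicate 1 (edgeR adjusted p from 0.122 to 0.291). Without WT replicate 2 the calls of Col1a1, Col3a1, Col5a2 and Postn ended (edgeR adjusted p from 0.0539 to 0.214), without Trbp-cKO replicate 1 those of Col3a1 (0.115) and Col5a2 (0.0911), and in DESeq2 that of Col5a2 (adjusted p = 0.0953).

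Lists of markers of other heart cell types had medians near 0. Among 10 fibroblast markers Gsn rose (594 ± 74.3 to 936 ± 14.2 CPM) and Col14a1 fell (85.5 ± 3.98 to 64.7 ± 6.55 CPM), 1 each adjusted over the list alone as well. Gsn lost its call without WT replicate 1 (edgeR adjusted p = 0.0638) and without Trbp-cKO replicate 2 (0.0591), and Col14a1 without WT replicate 1 (0.179) or 2 (0.102) and without Trbp-cKO replicate 1 (0.0620). Of 11 endothelial markers 1 rose, the receptor gene Tek (log2 fold change 0.29 ± 0.07), also adjusted over the list alone, and that call was lost with DESeq2 (adjusted p = 0.106), without WT replicate 1 or 2 (edgeR adjusted p = 0.212 and 0.214) and without Trbp-cKO replicate 1 (0.0796). No member passed among 10 smooth muscle and pericyte markers, 15 macrophage and leukocyte markers, 5 atrial markers or 2 fat markers, in edgeR or DESeq2, nor adjusted over the list alone. At an unadjusted edgeR p under 0.05 there were 2, 2, 1 and 0 genes. Medians were -0.03 for fibroblasts, 0.07 for endothelium, 0.08 for smooth muscle and pericytes, -0.04 for macrophages and leukocytes, and 0.16 for atrial genes. The members with the smallest p in the lists with no call were the smooth muscle and pericyte genes Abcc9 (0.20 ± 0.08) and Cspg4 (0.25 ± 0.10), the macrophage genes Cd14 (0.69 ± 0.20) and Cd163 (0.38 ± 0.12), and the atrial genes Stard10 (0.68 ± 0.20) and Myl4 (0.77 ± 0.45). Of these, Cd14 (edgeR adjusted p = 0.0198) and Stard10 (0.0351) passed with no filter, and Stard10 (0.00422) and Cspg4 (0.0158) without Trbp-cKO replicate 1. Without Trbp-cKO replicate 1 or 2 the log2 fold change was 0.95 or 0.34 for Stard10, 0.40 or 0.10 for Cspg4 and 1.15 or 0.23 for Myl4. Without WT replicate 1 or 2 that of Myl4 was 0.31 or 1.33, and without WT replicate 1 that of Abcc9 was 0.12. Camera set none of the 5 lists with 3 or more tested genes apart, with adjusted p from 0.412 to 0.916.

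**Figure D2:**
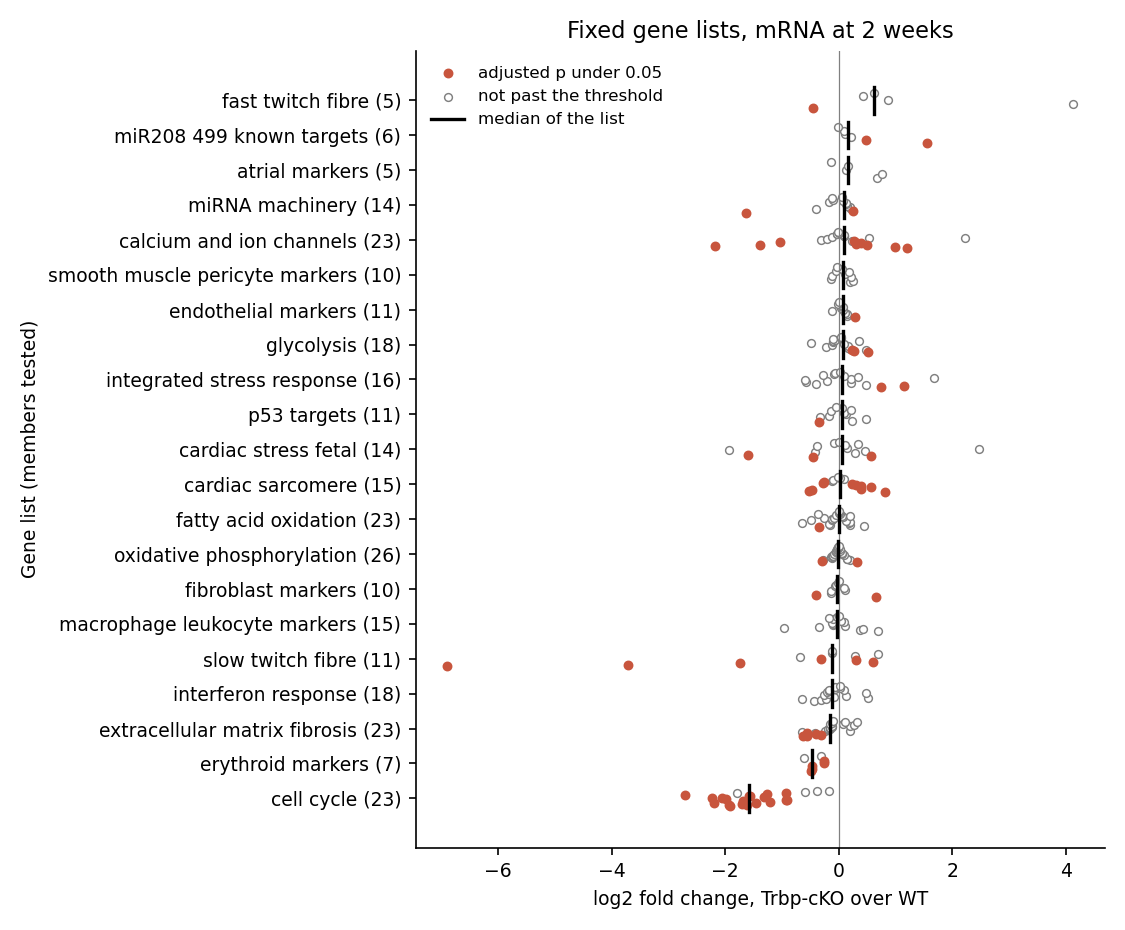
Log2 fold change, Trbp-cKO over WT, of each tested member of the 21 gene lists with 3 or more tested genes at 2 weeks. Filled points passed an adjusted p of 0.05 over all genes (edgeR), open points did not, and the black bar is the list's median, which was -1.57 for the cell-cycle list and -0.47 for the erythroid list.

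Genes of ion channels and calcium handling changed in both directions, 7 of 23 upward and 3 downward (9 and 5 adjusted over the list alone). Kcnip2, the auxiliary subunit of the transient outward potassium current, rose 2.30-fold from 50.7 ± 5.53 to 116 ± 6.34 CPM (edgeR adjusted p = 8.64e-05). The T-type calcium channel gene Cacna1g rose 1.99-fold from 93.6 ± 6.93 to 186 ± 10.0 CPM. Hcn4 fell as given above, to 2.47 ± 0.315 CPM. Kcnd2, a pore subunit of the transient outward current, fell 2.63-fold from 52.3 ± 5.09 to 19.9 ± 4.66 CPM, and was not called without WT replicate 1 (edgeR adjusted p = 0.0512). Kcne1, a potassium channel subunit gene, fell by 1.04 on the log2 scale and was not called without Trbp-cKO replicate 1 (edgeR adjusted p = 0.182) or 2 (0.127). Camera did not set the list apart (adjusted p = 0.357).

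Of 6 tested known targets of miR-208 and miR-499, 2 rose and none fell (3 rose adjusted over the list alone). Sox6 (chromosome 7, 115470872 to 116040776), a transcription factor that represses slow-fibre genes, rose 2.95-fold from 39.9 ± 0.746 to 118 ± 6.08 CPM (log2 fold change 1.56 ± 0.07, edgeR adjusted p = 5.24e-06). Med13 (chromosome 11, 86267033 to 86357596), a subunit of the Mediator complex, rose 1.40-fold from 119 ± 6.32 to 166 ± 6.97 CPM, and lost its call without WT replicate 2 (edgeR adjusted p = 0.0902). Purb (0.23 ± 0.07), Sp3 (0.11 ± 0.07), Cbx1 (0.09 ± 0.10) and Gja5 (-0.01 ± 0.15) did not pass, though Purb did without Trbp-cKO replicate 1 (edgeR adjusted p = 0.0436), and without Trbp-cKO replicate 1 Sp3 was at 0.06. Camera put the list higher than other genes (adjusted p = 4.87e-04), with an adjusted p of 0.484 with an estimated correlation.

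Metabolic lists showed few changes. In glycolysis 3 of 18 rose (3 adjusted over the list alone), namely the insulin-responsive glucose transporter gene Slc2a4 (315 ± 6.51 to 453 ± 7.95 CPM), Gpi1 (380 ± 0.429 to 457 ± 8.62 CPM) and Pfkm (877 ± 7.12 to 1036 ± 24.4 CPM). All 3 lost their calls without WT replicate 1 and without WT replicate 2, with edgeR adjusted p from 0.0580 to 0.326. Pfkm was also not called with DESeq2 size factors (edgeR adjusted p = 0.0502), with total count scaling (0.0882) or at a mean of at least 5 CPM (0.0596), nor Gpi1 with total count scaling (0.0667). Of 23 fatty acid oxidation genes Eci1 fell by 0.35 on the log2 scale, with no call adjusted over the list alone. Of 26 oxidative phosphorylation genes Cox6a2 rose (0.33 ± 0.07) and Cox7a1 fell (-0.29 ± 0.07), 1 each adjusted over the list alone. Eci1, Cox6a2 and Cox7a1 lost their calls without WT replicate 1 or 2 (edgeR adjusted p from 0.0715 to 0.326), Eci1, which was at -0.22 without WT replicate 2, also without Trbp-cKO replicate 1 (0.130) or 2 (0.159), and Cox7a1 without Trbp-cKO replicate 2 (0.0696). In the integrated stress response list 2 of 16 rose (2 adjusted over the list alone), the folate enzyme gene Aldh1l2 (53.7 ± 3.59 to 90.4 ± 9.40 CPM) and Chac1 (log2 fold change 1.14 ± 0.20). Chac1 was not called without WT replicate 1 or 2 (edgeR adjusted p = 0.126 and 0.109). Of 11 p53 targets Aen fell by 0.34 (1 rose and 1 fell adjusted over the list alone), a call lost with DESeq2 (adjusted p = 0.384) and without any 1 of the 4 libraries (edgeR adjusted p from 0.0980 to 0.205). None of 18 interferon response genes passed in edgeR or DESeq2, and 1 had an unadjusted edgeR p under 0.05, Ifit2 (-0.44 ± 0.17), which was at -0.25 without WT replicate 2 and at -0.27 without Trbp-cKO replicate 2. Camera gave these lists adjusted p from 0.357 to 0.996, and the list of miRNA-processing genes 0.916. Without WT replicate 1 it placed the interferon list lower (camera adjusted p = 0.00259).

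Over all 13625 genes tested, 1277 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 705 higher and 572 lower in Trbp-cKO. Of these, 93 were at least 2-fold higher and 198 at least 2-fold lower. With library sizes scaled by total count alone the split was 541 higher and 726 lower. DESeq2 called 747 genes, of which 682 were among the 1277, and leaving out WT replicate 1 or 2 brought the count in edgeR to 275 or 297.

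Small RNA libraries at postnatal day 2.5 were compared to ask which miRNAs differed in level between the genotypes. Muscle miRNAs encoded within myosin heavy chain genes were lower in Trbp-cKO. miR-499-5p (chromosome 2, 155622880 to 155622958, within Myh7b) fell 11.2-fold from 2575 ± 454 to 230 ± 56.3 CPM (n = 3 each, edgeR adjusted p = 1.46e-06), and miR-499-3p fell 7.82-fold. miR-208a-3p (chromosome 14, 54949060 to 54949142, within Myh6) fell 6.63-fold from 1518 ± 341 to 229 ± 2.03 CPM, and miR-208a-5p fell 4.17-fold. miR-208b-3p (chromosome 14, 54975700 to 54975776, within Myh7), which was more abundant, fell 1.83-fold from 35400 ± 8090 to 19366 ± 2372 CPM.

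The myomiR list, which gathers miRNAs expressed mainly in striated muscle, had 10 tested arms, of which 7 fell and 1 rose (the same adjusted over the list alone). miR-133b-3p fell 2.20-fold from 17.4 ± 2.82 to 7.90 ± 1.75 CPM, and miR-208b-5p fell from 15.9 ± 4.34 to 8.35 ± 1.96 CPM. miR-1a-1-5p rose from 8.43 ± 0.0327 to 14.9 ± 0.743 CPM. Its call was lost with no filter (edgeR adjusted p = 0.0527) and with DESeq2 (adjusted p = 0.0952), and that of miR-208b-5p as well (DESeq2 adjusted p = 0.118). Without any 1 of the libraries other than WT replicate 1, neither passed, with edgeR adjusted p from 0.0584 to 0.110 for miR-1a-1-5p and from 0.0530 to 0.207 for miR-208b-5p. miR-133b-3p was not called without Trbp-cKO replicate 1 (edgeR adjusted p = 0.0512). miR-486-5p (-0.06 ± 0.14) and miR-486-3p (-0.21 ± 0.18) did not pass, and miR-486-3p lay between -0.36 without WT replicate 3 and -0.08 without Trbp-cKO replicate 3. The main arms of miR-1a and miR-133a, whose hairpins exist in several near-identical copies, held 0 to 5 counts per library for each copy and gave no usable value. The 5p arm of the other miR-1a copy, miR-1a-2-5p, went the other way from miR-1a-1-5p at few counts. It held 4 to 8 counts per WT library and 0 to 2 per Trbp-cKO library. Matching by exact name left miR-133a-1-5p out of the list (-0.69, edgeR adjusted p = 0.0839). Camera put the list lower than other miRNAs (adjusted p = 4.56e-09), and the adjusted p was 0.0647 with an estimated correlation. Both arms of miR-208a, miR-208b, miR-499 and miR-486 count as separate members. The counts and camera thus rest on fewer separate hairpins than 10.

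**Figure D3:**
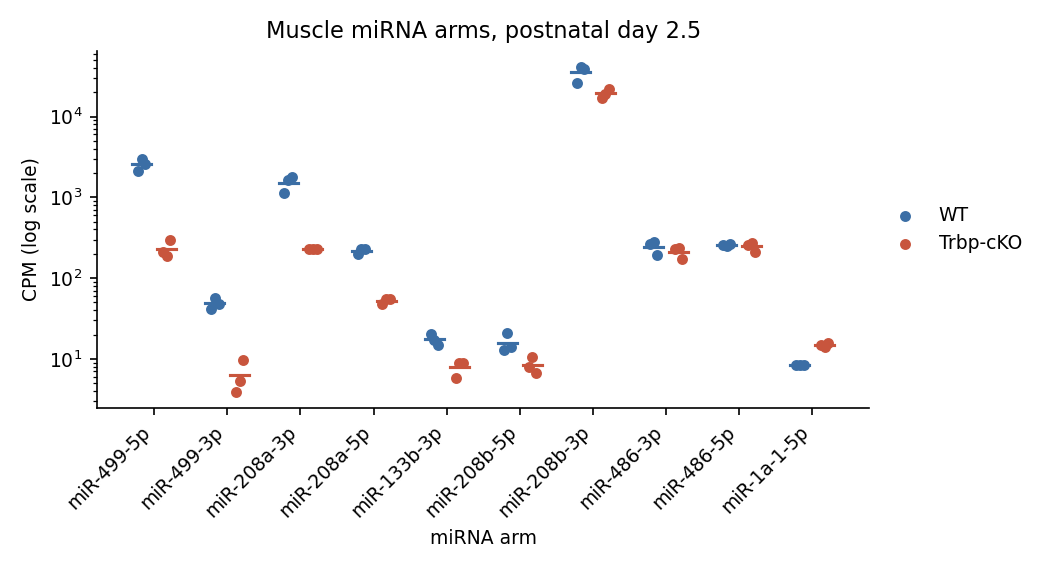
CPM on a log axis of the 10 tested arms of the muscle miRNA list in each small RNA library at postnatal day 2.5, with points for libraries (n = 3 per genotype) and short bars for the genotype means. miR-499-5p went from 2575 to 230 CPM and miR-208a-3p from 1518 to 229 CPM, while miR-486-5p was at 258 CPM in WT and 247 CPM in Trbp-cKO.

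Outside that list the deepest fall was in miR-504-5p (chromosome X, 59097658 to 59097736, within Fgf13), which went from 196 ± 42.5 to 7.66 ± 3.09 CPM (25.3-fold, edgeR adjusted p = 6.27e-07). miR-194-1-5p fell 12.3-fold from 62.9 ± 23.6 to 5.14 ± 2.04 CPM, and since that hairpin has another genomic copy its count is uncertain, as is that of miR-450a-1. miR-143-5p fell 5.09-fold and miR-490-5p 3.02-fold. The largest of the named rises were in miR-145a-3p (5.62-fold, 487 ± 171 to 2734 ± 513 CPM), miR-361-3p (4.36-fold, 89.2 ± 11.5 to 389 ± 47.8 CPM) and miR-22-5p (3.70-fold, 34.9 ± 5.87 to 130 ± 8.87 CPM). miR-378a-5p rose 3.27-fold, miR-30d-3p 3.19-fold, miR-30a-3p 3.17-fold, miR-15a-3p 3.10-fold and miR-450a-1-3p 2.72-fold. The edgeR adjusted p of these 12 arms was at most 0.00483, the value for miR-15a-3p.

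Other miRNA lists held few changes among the arms matched to them. Matching was by exact name, so tested arms of numbered hairpin copies, such as let-7f-2-5p and miR-199a-2-3p, were left out. Of 7 smooth muscle and fibroblast arms 2 rose (2 adjusted over the list alone), miR-145a-3p and miR-21a-5p, the second from 11678 ± 996 to 16065 ± 685 CPM. The miR-21a-5p call was lost without WT replicate 2 or 3 and without Trbp-cKO replicate 1 or 2 (edgeR adjusted p from 0.0532 to 0.0832). In the let-7 family let-7e-5p fell from 872 ± 53.1 to 528 ± 17.5 CPM (1 of 6, and 2 adjusted over the list alone), and in the miR-17-92 clusters miR-106b-5p fell from 350 ± 32.4 to 166 ± 14.9 CPM (1 of 7, and 1 adjusted over the list alone). Among 8 blood cell miRNAs miR-155-5p fell from 49.7 ± 1.36 to 28.6 ± 9.33 CPM (1 adjusted over the list alone), a call lost without WT replicate 2 or 3 and without Trbp-cKO replicate 2 or 3 (edgeR adjusted p from 0.0517 to 0.0771). None of 4 miR-30, 2 miR-29, 8 endothelial or 37 Dlk1-Dio3 cluster arms passed in edgeR, nor adjusted over the list alone. At an unadjusted edgeR p under 0.05 there were 1, 0, 1 and 3 of them, and DESeq2 called 1, 0, 1 and 0. The arms with the smallest p were miR-30a-5p (0.29 ± 0.12) and miR-30b-5p (0.18 ± 0.10), the endothelial miR-222-3p (-0.72 ± 0.25) and miR-23b-3p (-0.17 ± 0.10), and miR-380-3p (-0.55 ± 0.17) and miR-127-3p (-0.38 ± 0.13) of the cluster. DESeq2's calls were miR-30a-5p (adjusted p = 0.0489) and miR-222-3p (adjusted p = 0.0411). In edgeR, miR-222-3p passed with no filter (adjusted p = 0.000516), with separate library sizes per arm (0.0463), without WT replicate 1 (0.0449, at a log2 fold change of -0.43) and without WT replicate 3 (0.0303). miR-380-3p passed in edgeR with no filter (adjusted p = 0.0393), with separate library sizes per arm (0.0210), without WT replicate 1 (0.0198) and without Trbp-cKO replicate 3 (0.0159). miR-127-3p passed with separate library sizes per arm (edgeR adjusted p = 0.0237) and without WT replicate 1 (0.0144), and miR-30a-5p without WT replicate 1 (0.0463). Camera set none of these 7 lists of 3 or more tested arms apart, with adjusted p from 0.184 to 0.875.

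In all, 67 of 401 tested arms passed an adjusted p of 0.05 in edgeR, 25 higher and 42 lower in Trbp-cKO. DESeq2 also called 67, of which 60 were the same arms. Without WT replicate 1 the count in edgeR was 116. On the log CPM scale WT replicate 1 correlated with WT replicates 2 and 3 at 0.985 and 0.986. WT replicates 2 and 3 correlated at 0.995, and Trbp-cKO pairs at 0.991 to 0.992. Whether this accounts for the higher count was not tested.

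A further comparison asked whether the share of the 5p and 3p arms of a hairpin differed between the genotypes, since a precursor yields a duplex of which usually one strand is kept. In miR-361 (chromosome X, 113074824 to 113074893, within Chm) the 5p arm held 66.9% ± 5.30 of the hairpin's counts in WT and 28.2% ± 3.83 in Trbp-cKO (n = 3 each, edgeR adjusted p = 7.88e-13). miR-361-3p rose while miR-361-5p was at a log2 fold change of -0.26 ± 0.16. The 5p share of miR-542 went the other way, from 29.0% ± 2.12 to 57.7% ± 2.60, and that of miR-194-1 went from 95.7% ± 2.45 to 50.8% ± 8.60. The lowest library held 7 counts of miR-194-1-5p, and the lowest for its 3p arm 6. That hairpin also has another genomic copy, so its share is uncertain. In miR-30d the 5p share fell from 98.6% ± 0.109 to 95.8% ± 0.375, in miR-378a it rose from 0.599% ± 0.107 to 1.98% ± 0.0426, and in miR-22 from 0.0320% ± 0.00822 to 0.122% ± 0.0153. These 6 hairpins had the smallest p-values, with an edgeR adjusted p of at most 1.17e-08. Of 134 hairpins with both arms tested, 31 passed, 10 toward the 5p arm and 21 toward the 3p arm. Leaving out WT replicate 2 or Trbp-cKO replicate 1 brought the count to 20, and without WT replicate 1 it was 46.

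**Figure D4:**
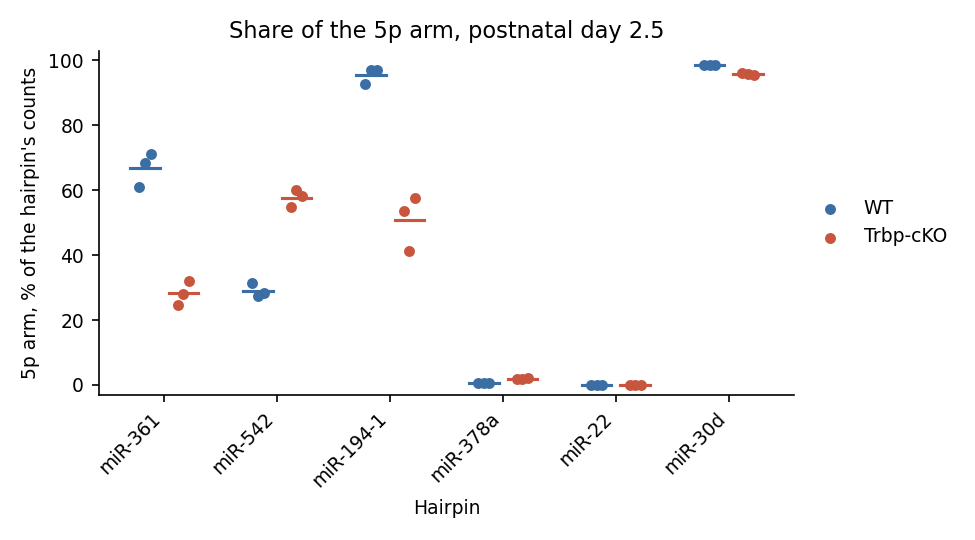
Share of the 5p arm in the counts of 6 hairpins, in percent, in each small RNA library at postnatal day 2.5, with points for libraries (n = 3 per genotype) and short bars for the genotype means. miR-361 went from 66.9% to 28.2% and miR-542 from 29.0% to 57.7%, while the changes in miR-378a and miR-22 lie under 2 percentage points.

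Comparison tables of the authors' own were deposited beside the counts. In the authors' deposited table for mRNA, 846 transcripts had a q-value under 0.01 and 746 of them formed the list of differential transcripts, which name 571 genes. Here 492 of these genes passed, out of 568 tested, 491 of them in the same direction. The authors' deposited table gave Myh7b a ratio of 0.00838, Tnnc1 0.0765, Tarbp2 0.319 and Sox6 2.94. Of the 60 miRNA arms in the authors' deposited table of differential arms, 54 passed an adjusted p of 0.05 here, and their directions were not compared.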

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

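The use of all transcripts, separate library sizes per arm and leaving out erythroid genes were chosen after seeing the data. The 1277 changed mRNAs became 1274 with DESeq2 size factors, 1267 with total count scaling, 1641 with no filter, 1053 at a mean of at least 5 CPM, 1271 without erythroid genes and 1334 with all transcripts. DESeq2 gave 747 genes, a difference whose cause was not tested, and an adjusted p of 0.01 gave 468, a stricter threshold by construction. Without 1 library each, 275 to 1171 genes passed, with fewer samples by construction and a lone library assumed to vary like the other genotype. Total count scaling moved the median of all genes by -0.04 on the log2 scale. Tarbp2 passed under every alternative, with log2 fold changes from -1.71 to -1.57. Of the mRNA lists 5 passed, and 0 with an estimated correlation, a test that the few degrees of freedom also weaken.

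The 67 miRNA arms became 66 to 78 under the other scalings, filters and tools, 46 at an adjusted p of 0.01, and 47 to 116 without 1 library. Leaving miR-143-3p out of library sizes gave 67 and separate library sizes per arm 72. Of the miRNA lists 1 passed, and 0 with an estimated correlation, under the same limit. The 31 hairpins of the arm test became 27 of 118 with at least 10 counts in each arm, and 20 to 46 without 1 library.

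The replicate number as a block gave 988 changed mRNAs, 63 arms, 38 hairpins, 7 mRNA lists and 2 miRNA lists, with Tarbp2 at -1.64. The added lists were fast-twitch (camera adjusted p = 6.52e-09), integrated stress response (0.0420) and smooth muscle miRNAs (0.0358). Deviations from the genotype means correlated between same-numbered libraries at 0.168 for mRNA and at 0.114, 0.0958 and 0.0445 for small RNA, across genes or arms, which are not independent. The samples share only a number. With the block, 13 of the 60 called mRNAs and 2 of the 24 called arms named by the rule did not pass (edgeR adjusted p from 0.0508 to 0.0969). The mRNAs were Sh2d4a, Col1a1, Col3a1, Col5a2, Tek, Mybpc2, Cox7a1, Gpi1, Aen, Eci1, Hbb-bt, Tnrc6c and Pfkm. The arms were miR-155-5p and miR-1a-1-5p. Of the 10 called items named after their values were seen 7 did not pass, namely Myl2, Atp2a2, Hbb-b2, Postn, Myom1, Actn2 and Fgf13 (edgeR adjusted p from 0.0546 to 0.108). Of those not called in the main fit, Tnni2 (edgeR adjusted p = 1.42e-05), Cacna1h (0.00410) and Acta1 (0.000904) passed and Nppa did not (0.417).

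Of 60 called named mRNAs other than Tarbp2, 29 kept direction and call under every alternative run, as did 19 of 24 named arms and the 6 named arm ratios. Of these 6 hairpins, miR-194-1 was not tested with at least 10 counts in each arm. The sign turned only in items that did not pass: Cbx1 without Trbp-cKO replicate 2 (-0.0206, the lowest without 1 library, the highest 0.185), Gja5 without WT replicate 1 (0.14, the highest, the lowest -0.160) or Trbp-cKO replicate 1 (0.13), and miR-486-5p without Trbp-cKO replicate 3 (0.0563, the highest, the lowest -0.144). At the depth, replicate number and common dispersion of these libraries, 44.7% of simulated 1.5-fold mRNA changes were recovered, among genes with a mean of at least 20 counts. Which of the 3 limits recovery was not tested. The planned comparison of seed-site genes was not run.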

Other observations

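The tests of blood, other cell types, host genes, a shared muscle factor, one shift of all 5p arms and the minor arm were chosen after the results were seen. Those of postnatal growth genes, a count minimum per arm and other splits were written before. Several genes with large differences did not pass in the main edgeR fit, and they are named after their values were seen. The fast skeletal troponin I gene Tnni2 was at 5.13 and 2.42 CPM in the WT libraries and at 86.5 and 50.7 CPM in the Trbp-cKO libraries (log2 fold change 4.13 ± 0.58, edgeR adjusted p = 0.0809). Nppa, the atrial natriuretic peptide gene, was at 68.9 and 66.4 CPM in WT and at 173 and 577 CPM in Trbp-cKO (2.47 ± 0.88, edgeR adjusted p = 0.307). Cacna1h, a T-type calcium channel gene, was at 9.35 and 3.97 CPM in WT against 37.1 and 27.0 CPM (2.23 ± 0.49, edgeR adjusted p = 0.126), and skeletal actin, Acta1, at 254 and 452 CPM against 78.5 and 107 CPM (-1.92 ± 0.46, edgeR adjusted p = 0.189). DESeq2 called all 4, with adjusted p of 4.38e-09 for Tnni2, 0.0319 for Nppa, 0.00780 for Cacna1h and 0.00117 for Acta1. In edgeR with the replicate number as a block, Tnni2 (adjusted p = 1.42e-05), Cacna1h (0.00410) and Acta1 (0.000904) passed and Nppa did not (0.417). The edgeR fits without 1 library take their spread from the 2 libraries of the other genotype alone, so that only effect sizes are given. Over these fits the log2 fold change lay between 3.70 and 4.82 for Tnni2, between 1.77 and 3.01 for Cacna1h and between -2.28 and -1.46 for Acta1. That of Nppa was 3.09 without Trbp-cKO replicate 1 and 1.35 without Trbp-cKO replicate 2.

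Genes whose annotated span holds a miRNA, here called hosts, were compared with that miRNA, at the different ages of the assays. Strand was not used, so genes on the other strand may be among them. Where a hairpin lay within several tested genes, the gene with the largest change was taken, a choice made on the values. Across 125 hairpins within a tested gene, Spearman's rho between the log2 fold changes was -0.07 (permutation p = 0.406) and Pearson's r was 0.28, which became -0.07 without miR-499. Hairpins are not independent replicates. Of 23 hairpins whose main arm fell, 1 had a host that fell, Myh7b, and 3 had a host that rose. One of the 3 was Chrm2, the cardiac muscarinic receptor gene, at 75.7 ± 5.89 CPM in WT and 149 ± 12.1 CPM in Trbp-cKO, while miR-490-3p within it fell from 621 ± 89.2 CPM by 1.00 on the log2 scale (edgeR adjusted p = 0.000303). The others were Fgf13, which holds miR-504, and Myh6, which holds miR-208a. Fgf13 (0.27 ± 0.07) was not called without any 1 of the 4 mRNA libraries (edgeR adjusted p from 0.0813 to 0.226), with total count scaling (0.0638) or in DESeq2 (adjusted p = 0.264), and Myh6 was not called without WT replicate 1 or 2 (edgeR adjusted p = 0.110 in both). These hosts were chosen after their values were seen. Apart from hosts, the arm in the majority changed in 3 hairpins that passed the arm test, miR-361, miR-542 and miR-145a, the last from 72.5% ± 8.91 to 33.0% ± 3.96 5p.

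Cell-cycle genes were lower in Trbp-cKO ventricles, with a median log2 fold change of -1.57. If Trbp-cKO hearts had been further along in postnatal growth, genes that decline steeply after birth, such as Igf2, H19 and Dlk1, would be lower, with a median of -0.5 or less and at least 3 in 4 below 0. Of 8 tested genes 6 lay below 0, but their median was -0.12 ± 0.13 (SE, taking genes as independent), above that bound by more than its SE. How far these genes fall near 2 weeks was not measured, so a smaller advance in growth is not excluded. Less blood alone is argued against, since it would lower all blood transcripts alike and the erythroid median was -0.47. That median is the value of the alpha globin copies, while Alas2 was at -0.48 and Hbb-bt at -0.25. A smaller share of a whole non-muscle cell type is argued against as well, since the lowest of the medians of fibroblast, endothelial, smooth muscle and leukocyte markers was -0.0374. Fewer dividing cells within any of these types, or in heart muscle, may still be the source, and a link to the deletion stays open as a hypothesis.

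miR-499 and miR-208a were both lower at postnatal day 2.5. Lower transcription of the host is a candidate explanation for miR-499, since Myh7b fell at 2 weeks (log2 fold change -6.89), but not in the same way for miR-208a, whose host Myh6 rose (0.39). Host levels at day 2.5 were not measured. A smaller share of muscle cells alone would lower muscle miRNAs by one factor. The log2 fold changes of miR-208b-3p (-0.87) and miR-208a-3p (-2.73) instead lay 1.86 apart, over 2 times their joined standard errors. Since both arms fell, a smaller share acting beside other effects is not excluded. An effect of Trbp on single precursors remains an untested hypothesis.

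Arm shares moved in both directions, with 10 of 31 hairpins gaining 5p, which argues against one shift of all 5p arms. With at least 10 counts in each arm in every library 22.9% of hairpins passed against 23.1% of all. That is not under 11.6%, the bound set for low counts as the source. Nor is it at least 23.1%, the bound set against it. Still, 27 of the 31 hairpins also passed at this minimum. This argues against arm counts under 10 as the source for these 27, and a part in the rest stays open. Of the 31 hairpins, 22 shifted toward the arm with fewer counts over all 6 libraries (exact two-sided binomial p = 0.0294), as did 80 of all 134 (p = 0.0304), treating hairpins as independent. The minor arm rose in 12 of the 22 and the major arm fell in 7, so that a gain of minor arms may be part of the pattern.

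The 6 small RNA libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 67 changed arms and 31 changed arm shares, while the highest of the other splits gave 0 for both, so that 1 of 10 splits gave as many. Every other split places both genotypes in each group. A genotype difference then widens the spread within groups and lowers the count, so the 0 is no evidence against chance. For the miRNA lists the real split gave 1 and the highest other split 3, and 5 of 10 splits gave as many or more.

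In the authors' deposited table, the 100 transcripts with a q-value under 0.01 that stand outside the list of differential transcripts had less even replicates. The median over transcripts of the larger log2 difference within a genotype was 1.69 for these and 0.46 for the list, computed here from the deposited counts plus 1. The counts were not scaled to library size, so that differences in depth enter both values. The WT libraries held 20841944 and 16056614 counts over all deposited transcripts.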
